A study of Mus musculus with 9 samples.

How the data were processed

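MH-S cells are a mouse alveolar macrophage line held by a cell repository, from the BALB/c strain per the labels. Total RNA from 3 control, 3 IL-4 and 3 LPS samples was hybridized to 1 Affymetrix mouse array each, biotin-labelled per the labels. The deposited values are signal intensities, 1 per probe set and array, on a linear scale. Per the labels, probe intensities were computed in GCOS 1.2, and the submitters' processing notes name MAS5 (Microarray Suite), which summarizes the probe pairs of a probe set into 1 signal. As deposited, each array's mean signal without the lowest and highest 2% was 499.8 to 499.9, so the arrays had been scaled to a common mean, read from the values. Such a scaling fixes the mean, not the median, and a few very bright probe sets on 1 array lower its other signals. Detection calls and scanner images were not used here. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

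The array held 45101 probe sets, of which 64 were controls. Gene names came from the platform's annotation, in which 34945 probe sets had 1 gene symbol, 932 several and 9160 none. Symbols were compared through Entrez identifiers with a table of mouse genes of the GRCm38.p6 assembly, used for names only, which changed 0 symbols, and 204 of the 1-symbol probe sets had no match there. Probe sets with several symbols were left out of the gene tests. Of the probe sets of a gene, the one with the highest mean over the 9 arrays was used, which left 18193 genes, 9010 of them with several probe sets.

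Signals were transformed as log2(signal + 23.2), where the offset is the 20th percentile of all signals. Fold changes are on this scale, which understates the changes of genes with low signals. Gene tests used limma's moderated test (lmFit and eBayes with an intensity trend, limma 3.58.1 in R 4.3.3), with 1 mean per group over all 9 arrays and no covariate. Benjamini-Hochberg adjustment ran within each comparison, and a gene was called at an adjusted p under 0.05. For n = 3 against 3, an exact test of a single gene cannot go below 0.1, so single genes rest on the moderated test, which borrows the spread from other genes. The 26 gene lists held 524 planned members, of which 480 were measured. They covered alternative activation, classical activation, inflammatory chemokines, interferon-stimulated genes, NF-kB targets and feedback, Toll-like receptor pathway, anti-inflammatory regulators, MHC class II presentation, MHC class I presentation, scavenger and phagocytic receptors, eicosanoid metabolism, arginine and polyamine metabolism, glycolysis, fatty acid oxidation, respiratory chain, cholesterol biosynthesis, cell cycle, oxidative stress response, unfolded protein response, matrix proteases and inhibitors, iron handling, alveolar macrophage identity, and markers of epithelium, of fibroblasts and endothelium, of lymphocytes and of neutrophils. They were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and again with the correlation estimated from the arrays. Adjustment ran over the 78 list tests, that is 26 lists in 3 comparisons. Some genes are on more than 1 list, so these tests are not independent.

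The genes named were picked by a rule. For IL-4 and for LPS against control it took the 10 called genes with the largest increase and the 10 with the largest decrease. For LPS against IL-4 it took the 5 each way. They had to have a mean signal above the median of all signals, 107.1, in at least 1 of the groups compared, and no overlap between the arrays of the groups. Added were up to 4 called members of each list with the largest changes, 20 marker genes whatever their test gave, and up to 10 genes called in opposite directions under IL-4 and LPS. Not all genes picked by this rule are given below. Groups, comparisons, lists, this rule and all alternatives were chosen before the data were examined, and any other gene is said to have been chosen after its values were seen.

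The code was tested on simulated data with the real genes' means and spread, in 5 runs with 200 changed genes of signal above the median among 18193. For IL-4 against control it recovered 81.6% of 2-fold and 99.4% of 4-fold changes, for LPS against control 83.2% and 99.6%, and for LPS against IL-4 78.8% and 99.4%. False calls made up 5.14%, 5.09% and 4.91% of the calls. With no list changed, camera called 0 of 26 lists, and a planted list was called in 5 of 5 runs. The planted list held only genes raised 2-fold or 4-fold and was judged at an unadjusted p under 0.05. Simulated genes varied independently of each other, so these runs cannot tell whether the preset correlation suits the real arrays. The simulated noise was normal, with the fit's own spread for each gene and equal on all arrays. Weights of the real arrays ran from 0.376 for IL-4 replicate 3 to 1.96 for LPS replicate 2. The false share of the runs therefore checks the code and does not measure that of the real calls. Unchanged groups were simulated 200 times, with simulated control arrays too, to measure what shared controls alone give.

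Background was read from the 27 control probe sets for bacterial genes, as their 95th percentile over the 9 arrays. Signals of 1 or lower occurred 94 times among all values. Signal ratios of the 3' to the 5' probe sets of Actb lay between 1.05 and 1.13 and those of Gapdh between 0.81 and 0.88 on the 9 arrays. In a principal component analysis of the 9 arrays the first component held 29.0% and the next 17.4% of the variance. The IL-4 arrays did not lie together on these components. IL-4 replicate 2, at -11.0 and 11.3, lay near control replicate 2, at -10.7 and 15.9. IL-4 replicates 1 and 3 lay at -28.5 and 24.7 and at -48.1 and -50.7. The number of arrays limits the precision of each value, and no depth applies.

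Alternatives changed 1 choice at a time: an offset of 1 or of 70.8 (the 40th percentile), a filter on genes with low signals, quantile normalization, centring on the array median, every probe set on its own (45037) or the mean of a gene's probe sets, no intensity trend, array weights, a fit of the 6 arrays compared, the replicate number as a block, an added 2-fold threshold, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.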

Results

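Transcript levels were measured in MH-S cells, a transformed line of mouse alveolar macrophages from the BALB/c strain, on 9 Affymetrix whole-genome expression arrays. Of these, 3 arrays held RNA of control cells, 3 of cells given IL-4 at 50 ng/ml and 3 of cells given LPS at 1 µg/ml, with RNA taken 12 h after either stimulus. The control arrays are labelled as uninfected control, with no time given, and were taken as untreated cells of the same experiment, on which every change against control depends. IL-4 is the T helper cell cytokine that drives alternative macrophage activation, and LPS is the bacterial cell wall component that drives classical activation through Toll-like receptor 4. The comparisons ask which transcripts each stimulus changed against control cells, how the 2 activated states differ from each other, and how far the changes run together. Each array carried 45101 probe sets, and 18193 genes were tested. The median signal of an array lay between 87.8 and 127.3, and the 27 control probe sets for bacterial genes, taken as background, had a 95th percentile of 71.3 over the 9 arrays, or 64.8 without IL-4 replicate 3. Their highest signal was 177.9, on IL-4 replicate 3, and 104.6 on the other 8 arrays. Signals under 71.3 are called the background range here, and the fold change of a gene from that range rests on the offset added before the logarithm. IL-4 replicate 3 stood apart from the other 8 arrays, with the highest maximum signal of 43636, a 99th percentile of 12244 against 7386 to 9103 on the others, and a geometric mean of the hybridization spike-ins of 4124 against 843 to 2033. IL-4 replicate 1 came next in each of these, at 21960, 9103 and 2033. IL-4 replicate 2 lay within the range of the control and LPS arrays, so the IL-4 arrays differed among themselves in brightness. The number of arrays, 3 per group, limits the precision of every value below.

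Large rises under IL-4 were those of Arg1, the arginase that converts arginine to ornithine, and Mrc1, the macrophage mannose receptor. The mean signal of Arg1 was 6.23 ± 2.91 (SD, n = 3) in control cells and 454 ± 42.9 under IL-4, a log2 change of 4.02 (SE 0.41, adjusted p = 0.000234). Mrc1 rose from 144 ± 27.7 to 1427 ± 107 (SD, n = 3), a log2 change of 3.13 (SE 0.19, adjusted p = 2.63e-06). The cytokine signalling inhibitor Cish rose by 2.46 (SE 0.18), the checkpoint ligand Cd274 by 2.14 (SE 0.11), the monocyte attractant Ccl12 by 2.20 (SE 0.11) and the growth factor Igf1 by 2.07 (SE 0.17), with adjusted p from 8.69e-07 to 4.23e-05. Tlr2, the receptor for bacterial lipoproteins, fell by 1.46 (SE 0.10, adjusted p = 9.35e-06), from 4444 ± 159 to 1609 ± 189 (SD, n = 3). The control signal of Arg1 lay in the background range, while that of Mrc1 lay above every bacterial probe set of the same array on 3 of 3 control arrays. With an offset of 1 their log2 changes were 6.05 and 3.31, and with the offset at the 40th percentile 2.77 and 2.81. The transcripts Gm15496 and Fndc7, from control signals in the background range, rose by 3.01 and 2.35, and with an offset of 1 by 3.64 and 3.58, more than Mrc1.

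In limma's moderated test, 240 genes differed between IL-4 and control cells, of which 157 were higher and 83 lower under IL-4. A change of at least 2-fold was found for 61 of the higher and 9 of the lower genes. Without adjustment 1977 genes had a p under 0.05, against 909.7 by chance, and the arrays of the groups did not overlap for 15.3% of all genes, against 10% by chance. The rise of Rnf19b, a RING finger protein, was 2.34 (SE 0.14, adjusted p = 2.63e-06). Among the transcripts that fell were Cybb, the catalytic subunit of the phagocyte NADPH oxidase, at -1.04 (SE 0.10, adjusted p = 0.000167), the integrin subunit Itga4 at -0.94 (SE 0.09, adjusted p = 0.000177) and Klhl6 at -1.09 (SE 0.13, adjusted p = 0.000934). The count was 151 without control replicate 1, with 106 higher and 45 lower, 114 without control replicate 2, with 87 and 27, and 135 without control replicate 3, with 102 and 33. It was 116 with each array centred on its median, with 69 higher and 47 lower, and 92 without the trend of variance with intensity, with 74 and 18. Without IL-4 replicate 3 it was 190, with 133 higher and 57 lower, of which 166 were among the 240. The lower genes also numbered 49 without IL-4 replicate 1 and 55 without LPS replicate 2, 49 in a fit of those 6 arrays alone and 54 with the replicate number as a block.

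Of the 29 measured genes listed for alternative activation, 10 rose and 0 fell, and 15 rose adjusted over the list alone. Its list test gave an adjusted p = 1.73e-17, and an adjusted p = 0.000918 with an estimated correlation. Besides Arg1, Mrc1 and Cish, the transcription factor Myc rose by 2.35 (SE 0.33, adjusted p = 0.00276) from a control signal in the background range, and by 3.01 with an offset of 1. Markers often used for this state were not called here, namely Retnla at 0.84 (SE 0.32), Chil3 at 0.26 (SE 0.51), Ccl17 at -0.14 (SE 0.47) and Ccl22 at -0.06 (SE 0.37), with adjusted p of 0.351 or higher. Their mean signals in the 3 groups were 69.4 or lower, in the background range. The IL-4 receptor chain Il4ra stood at 0.60 (SE 0.19, adjusted p = 0.222). Of the anti-inflammatory regulators, 6 of 21 rose and 0 fell (8 and 3 adjusted over the list alone). Set against other genes, the list had an adjusted p = 0.000106, and an adjusted p = 0.0213 with an estimated correlation. They included Cish, the phosphatase Dusp4 at 1.11 (SE 0.11) and the repressor Nfil3 at 1.08 (SE 0.16). Cish and Socs1 are also on the alternative activation list, so the results of these 2 lists are not independent. The signalling inhibitor Socs1 was also called, at 2.22 (SE 0.39, adjusted p = 0.0126), from a mean control signal of 54.5, in the background range. With an offset of 1 the change of Socs1 was 2.79, and with the offset at the 40th percentile 1.62. Its adjusted p was 0.0722 without control replicate 2, 0.0596 without control replicate 3, 0.0518 without IL-4 replicate 2 and 0.0556 without the intensity trend.

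As a group, the interferon-stimulated genes stood lower under IL-4, with a median log2 change of -0.15, or -0.0994 without IL-4 replicate 1 (adjusted p = 0.00433). Of 33 measured, 0 rose and 2 fell, and 8 fell adjusted over the list alone. For this list the test gave adjusted p = 4.33e-05, and adjusted p = 0.0388 with an estimated correlation. The antiviral effector Ifit3 fell by 0.62 (SE 0.10, adjusted p = 0.00668). It was -0.59 with an adjusted p = 0.0601 without control replicate 2 and had an adjusted p = 0.0869 without the intensity trend. The call of Ifit1 at -0.44 (SE 0.09, adjusted p = 0.0437) held in 1 of the 9 fits that leave out an array, and its adjusted p reached 0.192 without control replicate 1. Of the inflammatory chemokines, 2 of 18 rose and 1 fell (4 and 2 adjusted over the list alone), and the list did not stand apart from other genes (adjusted p = 0.266). Its risers were Ccl12 and Ccl7, at 1.60 (SE 0.17), both attractants of monocytes, while the interferon-inducible T cell attractant Cxcl10 fell by 0.83 (SE 0.11, adjusted p = 0.00182). Of the classical activation genes, 3 of 28 rose and 1 fell (4 and 5 adjusted over the list alone), with an adjusted p = 0.70 for the list. The cytokine Il1b rose by 1.13 (SE 0.12, adjusted p = 0.000257). The inflammatory cytokine Tnf, at -1.06 (SE 0.25, adjusted p = 0.0654), was not called over the 9 arrays. It was called at -1.38 with an adjusted p = 0.00713 without IL-4 replicate 2, and with an adjusted p = 0.0348 after the filter on low values. Nos2, Il6 and Il12b, with log2 changes of 0.12, -0.23 and -0.18, were not called. In control cells Nos2 and Il6 read 51.3 ± 34.5 (SD, n = 3) or lower, in the background range, while Il12b read 84.7 ± 12.4 and lay above every bacterial probe set of the same array on 3 of 3 arrays. Il10 at 0.17 (SE 0.23), Tlr4 at 0.24 (SE 0.10), Marco at -0.01 (SE 0.31) and the LPS co-receptor Cd14 at -0.24 (SE 0.15) were not called either. Of these, Marco lay in the background range, above every bacterial probe set of the same array on 0 of 3 control and 0 of 3 IL-4 arrays. After quantile normalization Cd14 was called at -0.54 with an adjusted p = 0.00585.

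In arginine and polyamine metabolism 2 of 15 rose and 0 fell (2 and 0 adjusted over the list alone). As a group they had an adjusted p = 0.00104, and an adjusted p = 0.0884 with an estimated correlation. The risers were Arg1 and the cationic amino acid transporter Slc7a2, at 1.64 (SE 0.15, adjusted p = 0.000137). Of the matrix proteases and inhibitors 3 of 21 rose and 0 fell (3 and 1 adjusted over the list alone), namely the collagenase Mmp13 at 1.49 (SE 0.14), the macrophage elastase Mmp12 at 0.91 (SE 0.10) and Adam8 at 0.75 (SE 0.11). The list's adjusted p = 0.025 became an adjusted p = 0.123 with an estimated correlation, 0.0757 without IL-4 replicate 1 and 0.0502 without IL-4 replicate 3. After quantile normalization it was 0.402, and the list's median turned from 0.11 to -0.05. That median was 0.20 without control replicate 1, 0.072 without control replicate 2, 0.30 without IL-4 replicate 2 and 0.072 without IL-4 replicate 3. For presentation on MHC class II, 1 of 12 rose and 0 fell (1 and 0 adjusted over the list alone), namely the invariant chain Cd74 at 1.16 (SE 0.18, adjusted p = 0.00526), whose adjusted p was 0.068 without the intensity trend. The list's adjusted p = 0.0135 became an adjusted p = 0.286 with an estimated correlation, 0.0582 without control replicate 3, 0.0502 without IL-4 replicate 3 and 0.114 after quantile normalization.

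Among genes of energy metabolism, 0 of 19 rose and 0 fell (2 and 1 adjusted over the list alone) for glycolysis, with a median of 0.33, and 0 of 19 rose and 0 fell (0 and 0 adjusted over the list alone) for the respiratory chain, with a median of 0.12. Without adjustment 4 in glycolysis and 1 in the respiratory chain had a p under 0.05. The list tests gave an adjusted p = 0.0455 for glycolysis and 0.0254 for the respiratory chain, and an adjusted p = 0.452 and 0.626 with an estimated correlation. Without IL-4 replicate 3, the array that stood apart, the medians were 0.09 (adjusted p = 0.278) and -0.03 (adjusted p = 0.747). After quantile normalization the medians were 0.04 (adjusted p = 0.242) and -0.04 (0.238). Neither list was called with median centring (adjusted p = 0.0793 and 0.152) or array weights (0.115 and 0.313), nor glycolysis with the offset at the 40th percentile (0.0591). Both calls also ended without control replicate 3, at medians of 0.16 and 0.061 with adjusted p of 0.362 and 0.288, and that of glycolysis without LPS replicate 1 (0.053) and LPS replicate 3 (0.0529). The glycolysis median was 0.19 without IL-4 replicate 1. In the unfolded protein response 1 of 19 rose and 0 fell (2 and 0 adjusted over the list alone). Tested together they had an adjusted p = 0.0399, and an adjusted p = 0.325 with an estimated correlation. That list's call also ended without control replicate 1 (0.0567), control replicate 3 (0.138), IL-4 replicate 2 (0.0694), IL-4 replicate 3 (0.166) or LPS replicate 3 (0.0584). It ended as well after quantile normalization (0.0638), with median centring (0.147) and with array weights (0.0994). Its called member, the disulfide isomerase Pdia4, was at 0.88 (SE 0.11, adjusted p = 0.000864), and at 0.24 with an adjusted p = 0.793 in the mean of its probe sets. That mean took in a probe set in the background range, with a mean signal of 54.6.

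Other lists of immune and metabolic genes did not stand apart from other genes under IL-4. Of the scavenger and phagocytic receptors 4 of 29 rose and 0 fell (4 and 2 adjusted over the list alone), with an adjusted p = 0.0883. That list was called without control replicate 2 (adjusted p = 0.0182) and after the filter on low values (0.0314). In the Toll-like receptor pathway 0 of 21 rose and 1 fell (0 and 1 adjusted over the list alone), the called gene being Tlr2 (adjusted p = 0.283 for the list), with a median of 0.00 and a mean of -0.04. Of the NF-kB targets 0 of 20 rose and 1 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.791). The list's median of 0.05 and mean of 0.02 lay above 0 while its test pointed down. Its called member, the atypical inhibitor Nfkbiz, fell by 1.17 (SE 0.19, adjusted p = 0.00841), with an adjusted p = 0.102 without the intensity trend. Iron handling had 1 higher and 2 lower of 14 (adjusted p = 0.818), and eicosanoid metabolism 1 higher and 0 lower of 20 (adjusted p = 0.301), the same numbers as adjusted over the list alone. The moderated test called 0 members of MHC class I presentation (list adjusted p = 0.11), fatty acid oxidation (0.607), cholesterol biosynthesis (0.643), cell cycle (0.568) or the oxidative stress response (0.946). Without adjustment 3, 1, 1, 3 and 3 members of these lists had a p under 0.05, and MHC class I presentation was called as a list without IL-4 replicate 1 (adjusted p = 0.0234). The oxidative stress list's median of 0.02 and mean of 0.09 lay above 0 while its test pointed down. Adjusted over the list alone, 1 gene of fatty acid oxidation fell and 1 of the oxidative stress response rose.

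**Figure D1:**
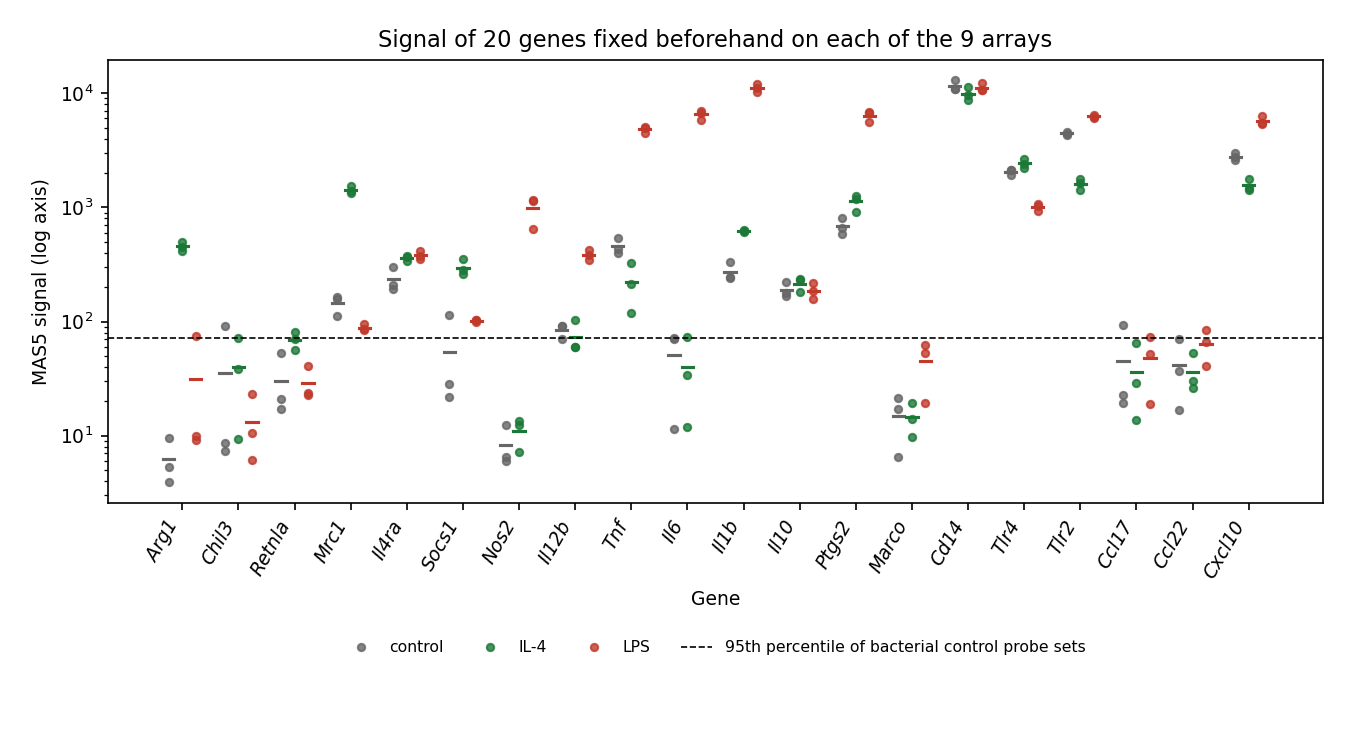
Array signals of the marker genes fixed in advance, on a log axis without units, for the control, IL-4 and LPS groups; dots are single arrays (n = 3 per group), bars are group means, and the dashed line is the 95th percentile of the bacterial control probe sets, 71.3. Arg1 and Mrc1 stand highest under IL-4, Nos2, Il6, Il1b and Tnf highest under LPS, and Chil3, Retnla, Ccl17 and Ccl22 have group means at or under 69.4 throughout.

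Large rises under LPS were those of the cytokine transcripts Il1a, Il6, Csf2 and Il1b. The mean signal of Il1a, the interleukin-1 alpha transcript, was 12.6 ± 1.51 (SD, n = 3) in control cells and 5950.4 ± 129 under LPS, a log2 change of 7.38 (SE 0.23, adjusted p = 1.31e-09). Il6 rose from 51.3 ± 34.5 to 6522 ± 602, by 6.59 (SE 0.40, adjusted p = 3.62e-07), and Il1b from 274 ± 52.1 to 11071 ± 899 (SD, n = 3), by 5.24 (SE 0.12, adjusted p = 1.07e-10). The myeloid growth factor Csf2 rose by 5.87 (SE 0.32), the inducible nitric oxide synthase Nos2 by 4.95 (SE 0.32), the neutrophil attractant Cxcl2 by 4.30 (SE 0.14) and Mmp13 by 4.33 (SE 0.14). Rnase4, a secreted ribonuclease, fell from 3169.9 ± 35.9 to 309.6 ± 1.08 (SD, n = 3), by 3.26 (SE 0.08, adjusted p = 1.65e-10). Control signals of Il1a, Il6, Csf2 and Nos2 lay in the background range, and with an offset of 1 their log2 changes were 8.78, 7.34, 7.54 and 6.73. With the offset at the 40th percentile they were 6.17, 5.79, 4.60 and 3.69, against 5.02 for Il1b.

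In limma's moderated test, 1393 genes differed between LPS and control cells, with 680 higher and 713 lower under LPS, and 217 of the higher and 167 of the lower changed at least 2-fold. Without adjustment 3295 genes had a p under 0.05, against 909.7 by chance, and the arrays of the groups did not overlap for 26.1% of genes, against 10% by chance. Among the genes that fell, the Ras activator Rasgrp3 stood at -2.80 (SE 0.09), the G protein regulator Rgs2 at -2.71 (SE 0.13), the protease inhibitor Serpinb1a at -2.47 (SE 0.16), the complement component C1qa at -2.38 (SE 0.11) and the eosinophil attractant Ccl24 at -2.31 (SE 0.17), with adjusted p of 1.79e-06 or lower. The transcript U90926 rose by 5.39 (SE 0.32, adjusted p = 2.92e-07) from a control signal in the background range, and by 6.70 with an offset of 1. The count was 912 without control replicate 2, with 454 higher and 458 lower, 955 without LPS replicate 1, with 451 and 504, 826 without the intensity trend, with 414 and 412, and 2140 with array weights, with 1037 and 1103. With each array centred on its median, 580 genes were higher and 357 lower, 61.9% higher against 48.8% in the deposited scaling.

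Of the classical activation genes 18 of 28 rose and 1 fell (19 and 1 adjusted over the list alone). The list had an adjusted p = 9.65e-24, and an adjusted p = 0.000765 with an estimated correlation. Besides Il1a, Il6, Csf2 and Il1b, the marker genes Tnf, at 3.35 (SE 0.25), and Il12b, the shared subunit of IL-12 and IL-23, at 1.92 (SE 0.27), rose. The member that fell was the costimulatory ligand Cd86, at -0.78 (SE 0.12, adjusted p = 0.00105), chosen after its values were seen. Of the NF-kB targets and feedback genes 16 of 20 rose and 0 fell (17 and 0 adjusted over the list alone). Its list test gave an adjusted p = 3.75e-28, and an adjusted p = 0.000765 with an estimated correlation. The negative regulator Irak3 rose by 2.94 (SE 0.09), the adaptor Traf1 by 1.86 (SE 0.25), the ubiquitin-editing enzyme Tnfaip3 by 1.78 (SE 0.14) and Nfkbiz by 2.19 (SE 0.19), while another probe set of Nfkbiz was at -0.28 and was not called. Of the inflammatory chemokines 9 of 18 rose and 0 fell (10 and 0 adjusted over the list alone). Set against other genes, the list had an adjusted p = 1.32e-08, and an adjusted p = 0.00538 with an estimated correlation. Besides Cxcl2, they included Cxcl3 at 4.61 (SE 0.33), Ccl5 at 1.29 (SE 0.14) and Cxcl11 at 1.31 (SE 0.23), and Cxcl10 rose by 1.03 (SE 0.11). The mean control signal of Cxcl3 was 27.8, in the background range. Its change was 5.46 with an offset of 1 and 3.70 with the offset at the 40th percentile. Of the interferon-stimulated genes 13 of 33 rose and 0 fell (17 and 0 adjusted over the list alone), with a median change of 0.32. For this list the test gave adjusted p = 1.15e-12, and adjusted p = 0.00536 with an estimated correlation. The guanylate-binding protein Gbp3 rose by 1.57 (SE 0.20), the exonuclease Isg20 by 1.34 (SE 0.17) and the antiviral GTPases Mx1 and Mx2 by 1.06 (SE 0.14) and 0.77 (SE 0.13).

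In the oxidative stress response 9 of 14 rose and 0 fell (11 and 0 adjusted over the list alone). As a group they had an adjusted p = 2.85e-16, and an adjusted p = 0.00536 with an estimated correlation. The cystine transporter Slc7a11 rose by 3.70 (SE 0.22), Gclm, a subunit of the glutathione synthesis enzyme, by 1.65 (SE 0.11) and heme oxygenase Hmox1 by 1.27 (SE 0.12). Of the anti-inflammatory regulators 7 of 21 rose and 1 fell (9 and 3 adjusted over the list alone). Tested together they had an adjusted p = 6.13e-07, and an adjusted p = 0.00718 with an estimated correlation. The inhibitory receptor Pilra rose by 3.25 (SE 0.25), the interleukin-1 receptor antagonist Il1rn by 2.19 (SE 0.11) and the TNF receptor Tnfrsf1b by 2.08 (SE 0.10), and the phosphatase Dusp1, chosen after its values were seen, fell by 0.43 (SE 0.09). Il10 stood at -0.01 (SE 0.23), Socs1 at 0.88 (SE 0.39), Arg1 at 0.68 (SE 0.41) and Mrc1 at -0.57 (SE 0.19, adjusted p = 0.0905), all not called. Mrc1 had an adjusted p = 0.0421 after the filter on low values and 0.0404 in the mean of its probe sets, and Socs1 had one of 0.0225 without control replicate 1. The Toll-like receptor pathway went both ways, as 2 of 21 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.818 for the list). Tlr4, the LPS receptor, fell by 1.01 (SE 0.10, adjusted p = 2.11e-05), from 2053 ± 116 to 1007 ± 78.6 (SD, n = 3). The kinase Irak2 rose by 0.98 (SE 0.09), and Tlr2 rose by 0.49 (SE 0.10) with an adjusted p of 0.00824, or 0.0606 without the intensity trend.

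In fatty acid oxidation the list median was -0.27, and 0 of 19 rose and 2 fell (1 and 9 adjusted over the list alone). The list had an adjusted p = 0.000938, and an adjusted p = 0.0388 with an estimated correlation. The called members were the carnitine palmitoyltransferase Cpt1a, at -0.68 (SE 0.09), and Etfdh, at -0.49 (SE 0.10). In the mean of their probe sets these had adjusted p of 0.087 and 0.803, and that of Etfdh was 0.178 with median centring and 0.0742 without the intensity trend. For Etfdh that mean took in a probe set in the background range, with a mean signal of 28.2. In cholesterol biosynthesis 0 of 20 rose and 5 fell (0 and 9 adjusted over the list alone), among them the synthase Hmgcs1 at -0.75 (SE 0.14). Its list test gave an adjusted p = 5.85e-05, and an adjusted p = 0.0643 with an estimated correlation. For Hmgcs1 the adjusted p was 0.0565 with median centring and 0.0549 without the intensity trend. In the cell cycle list 0 of 31 rose and 6 fell (0 and 7 adjusted over the list alone), including cyclin D1 (Ccnd1) at -0.74 (SE 0.12), the mitotic kinase Plk1 at -0.73 (SE 0.09), the proliferation marker Mki67 at -0.67 (SE 0.12) and the spindle motor Kif11 at -0.66 (SE 0.08). Set against other genes, the list had an adjusted p = 0.000778, and an adjusted p = 0.142 with an estimated correlation. For the respiratory chain 0 of 19 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.22 and 5 at an unadjusted p under 0.05. For this list the test gave adjusted p = 0.000947, and adjusted p = 0.452 with an estimated correlation. In glycolysis 5 of 19 rose and 1 fell (6 and 2 adjusted over the list alone). As a group they had an adjusted p = 0.00263, and an adjusted p = 0.302 with an estimated correlation. Hexokinase 2 (Hk2) rose by 1.45 (SE 0.10) and the lactate transporter Slc16a3 by 1.44 (SE 0.22).

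In arginine and polyamine metabolism 4 of 15 rose and 0 fell (4 and 0 adjusted over the list alone). Tested together they had an adjusted p = 0.000106, and an adjusted p = 0.0571 with an estimated correlation. These were led by Nos2, Slc7a2 at 2.63 (SE 0.15) and Gch1, which makes the synthase's cofactor, at 1.52 (SE 0.09). In iron handling 3 of 14 rose and 1 fell (5 and 1 adjusted over the list alone). The list had an adjusted p = 0.0080, and an adjusted p = 0.178 with an estimated correlation. The siderophore-binding Lcn2 rose by 1.52 (SE 0.16). In the unfolded protein response 4 of 19 rose and 1 fell (6 and 1 adjusted over the list alone), including the pseudokinase Trib3 at 1.52 (SE 0.09) and Chac1, which degrades glutathione, at 0.94 (SE 0.14). The list had an adjusted p = 0.0126, an adjusted p = 0.245 with an estimated correlation, and 0.0564 without control replicate 3. For presentation on MHC class I 2 of 15 rose and 0 fell (5 and 0 adjusted over the list alone). Its list test gave an adjusted p = 0.00262, and an adjusted p = 0.236 with an estimated correlation. Its called members Tapbpl and Tap1, at 0.74 (SE 0.11) and 0.47 (SE 0.10), had adjusted p of 0.903 and 0.842 in the mean of their probe sets. That of Tap1 was 0.0635 without control replicate 1, 0.0698 without LPS replicate 2 and 0.0878 without the intensity trend.

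Other lists of immune genes did not stand apart under LPS. Of the scavenger and phagocytic receptors 2 of 29 rose and 5 fell (3 and 7 adjusted over the list alone; adjusted p = 0.23), with the beta-glucan receptor Clec7a at -1.66 (SE 0.10), the Fc receptor Fcgr3 at -1.63 (SE 0.12), the collectin Colec12 at -1.19 (SE 0.14) and the formyl peptide receptor Fpr2 at 2.84 (SE 0.30). Of the matrix proteases and inhibitors 5 of 21 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0546), led by Mmp13, Mmp9 at 3.20 (SE 0.16) and Mmp12 at 2.11 (SE 0.10). The median of that list, -0.01, lay below 0 while its mean of 0.39 and its test pointed up. It was called without control replicate 1 (adjusted p = 0.0415), LPS replicate 1 (0.0473) or LPS replicate 2 (0.0342). In eicosanoid metabolism 4 of 20 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.318), with cyclooxygenase 2 (Ptgs2) at 3.18 (SE 0.14), prostaglandin E synthase Ptges at 1.34 (SE 0.26) and thromboxane synthase Tbxas1 at -0.85 (SE 0.15). Of the alternative activation genes 3 of 29 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.946), with a median of 0.00, a mean of -0.04 and a test pointing down. For MHC class II presentation 0 of 12 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.249). Retnla, Chil3, Ccl17, Ccl22, Marco and Cd14 were not called, with log2 changes of 0.00, -0.42, 0.14, 0.49, 0.79 and -0.06. All but Cd14 had group means in the background range. The change of Marco was 1.51 with an offset of 1 and 0.42 with the offset at the 40th percentile. Il4ra was called at 0.67 (SE 0.19, adjusted p = 0.047). That call held in 2 of the 9 fits that leave out an array, with adjusted p up to 0.17 without control replicate 3, and Il4ra was at 0.24 with an adjusted p = 0.593 in the mean of its probe sets.

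**Figure D2:**
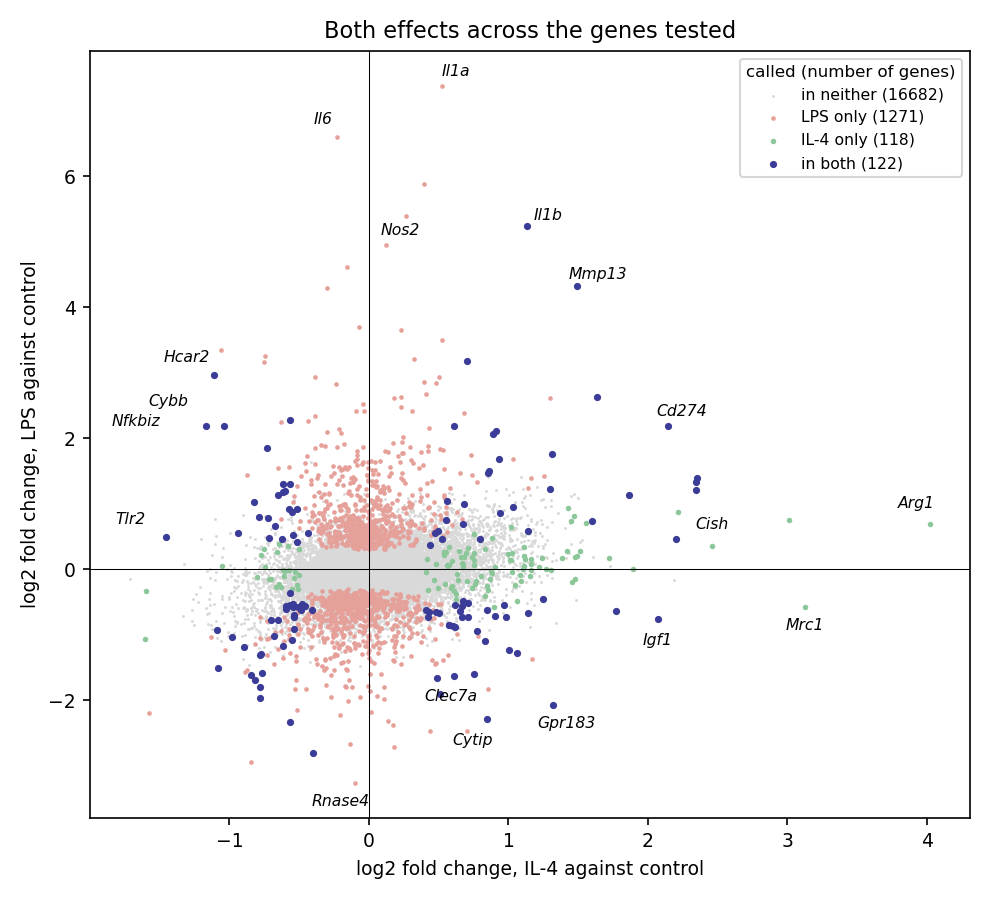
Log2 change under LPS against log2 change under IL-4, each relative to control cells, for all 18193 genes (1 dot per gene, means of 3 arrays per group); colours mark the 118 genes called under IL-4 only, the 1271 called under LPS only and the 122 called under both. Arg1 and Mrc1 lie far to the right near a log2 LPS change of 0.68 and -0.57, and Il1a and Il6 lie far up near an IL-4 change of 0.52 and -0.23.

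Set directly against each other, LPS-treated cells held far more Il1a, Il6 and Nos2 transcript and IL-4-treated cells far more Mrc1 and Arg1. Il1a was higher under LPS by 6.86 (SE 0.23, adjusted p = 2.18e-09), Il6 by 6.82 (SE 0.40, adjusted p = 2.08e-07) and Nos2 by 4.83 (SE 0.32, adjusted p = 6.53e-07), from signals in the background range under IL-4. Mrc1 read 88.3 ± 5.33 under LPS and 1427 ± 107 under IL-4 (SD, n = 3), a log2 difference of -3.70 (SE 0.19, adjusted p = 5.91e-08). The oxysterol-sensing receptor Gpr183 differed by -3.39 (SE 0.09, adjusted p = 2.77e-10), with 369 ± 18.0 under LPS and 4095 ± 232 under IL-4 (SD, n = 3), and Arg1 by -3.34 (SE 0.41, adjusted p = 0.000146). With the 40th percentile of all signals as the offset, the differences of Il1a, Il6, Nos2, Mrc1 and Arg1 were 5.92, 5.93, 3.64, -3.23 and -2.42.

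In limma's moderated test, 2085 genes differed between LPS and IL-4, with 1128 higher and 957 lower under LPS, and 259 of the higher and 307 of the lower differed at least 2-fold. Without adjustment 4452 genes had a p under 0.05, against 909.7 by chance, and the arrays of the groups did not overlap for 27.9% of genes, against 10% by chance. Other genes far higher under LPS were Csf2 at 5.48 (SE 0.32), Tnf at 4.41 (SE 0.25) and Cxcl3 at 4.77 (SE 0.33), and others far lower were Rnase4 at -3.16 (SE 0.08), Igf1 at -2.83 (SE 0.17) and the VEGF receptor Flt1 at -2.40 (SE 0.10). The count was 1289 without LPS replicate 1, with 684 higher and 605 lower, 1331 without LPS replicate 2, with 698 and 633, 1285 without the intensity trend, with 650 and 635, and 1870 without IL-4 replicate 3. Median centring of the arrays moved the median of all genes by 0.19 in this comparison, by -0.10 for IL-4 and by 0.09 for LPS against control. With that scaling 1608 genes were higher and 424 lower, 79.1% higher against 54.1% in the deposited scaling.

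Of the alternative activation genes 12 of 29 were lower under LPS than under IL-4 and 1 higher (15 and 1 adjusted over the list alone). Set against other genes, the list had an adjusted p = 2.92e-07, and an adjusted p = 0.00629 with an estimated correlation. Besides Mrc1 and Arg1, these were led by Ccl24 at -2.45 (SE 0.17) and Flt1, and the member that was higher was Mmp12 at 1.20 (SE 0.10). Of the classical activation genes 19 of 28 were higher and 0 lower (21 and 0 adjusted over the list alone). For this list the test gave adjusted p = 5.19e-22, and adjusted p = 0.000765 with an estimated correlation. Of the NF-kB targets 15 of 20 were higher and 0 lower (17 and 0 adjusted over the list alone), with Irak3 at 3.32 (SE 0.09). As a group they had an adjusted p = 3.16e-20, and an adjusted p = 0.000918 with an estimated correlation. Of the interferon-stimulated genes 19 of 33 were higher and 0 lower (23 and 0 adjusted over the list alone), with Gbp3 at 2.14 (SE 0.20) and Ifit3 at 1.08 (SE 0.10). Tested together they had an adjusted p = 3.30e-16, and an adjusted p = 0.00352 with an estimated correlation. In the oxidative stress response 10 of 14 were higher and 1 lower (11 and 1 adjusted over the list alone), with catalase (Cat) at 1.44 (SE 0.20). The list had an adjusted p = 1.69e-12, and an adjusted p = 0.00718 with an estimated correlation. The lower member of that list was the quinone reductase Nqo1, at -1.32 (SE 0.29), chosen after its values were seen.

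**Figure D3:**
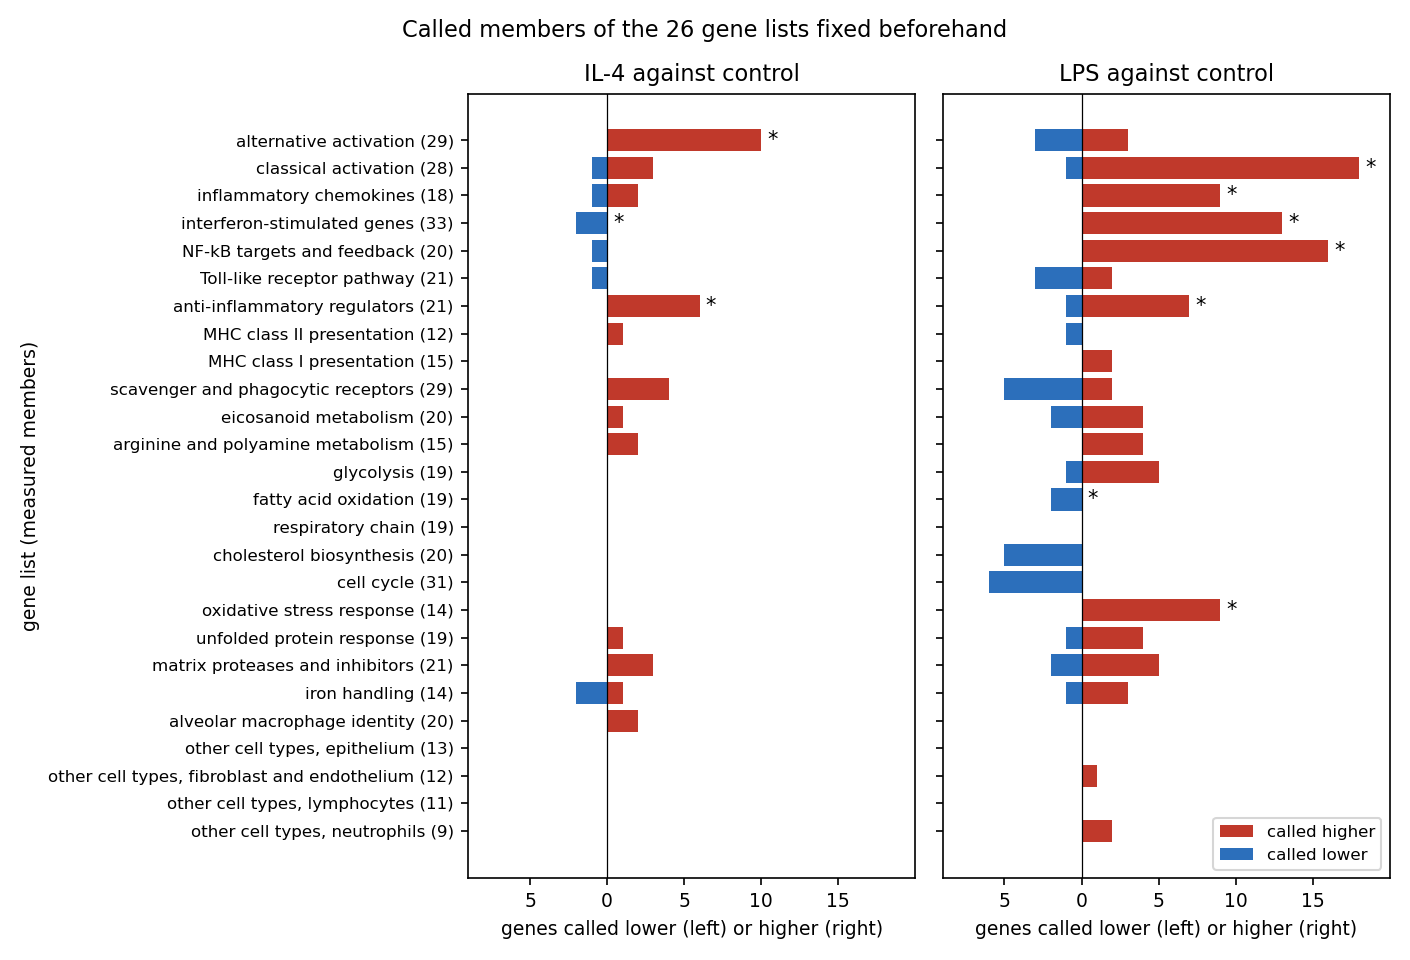
Number of genes called higher (bars to the right) or lower (bars to the left) in each of the 26 gene lists, for IL-4 against control and LPS against control. Measured members are given in brackets. An asterisk marks a list past the threshold of the list test both with the preset and with an estimated correlation. Under IL-4, 3 lists carry an asterisk, and under LPS 7.

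Further lists were called between LPS and IL-4 with the preset correlation only. The inflammatory chemokines had 7 higher and 2 lower of 18 (8 and 4 adjusted over the list alone), with Cxcl10 at 1.86 (SE 0.11) and Ccl12 at -1.74 (SE 0.11). Its list test gave an adjusted p = 0.00722, and an adjusted p = 0.0726 with an estimated correlation. MHC class II presentation had 0 higher and 3 lower of 12 (0 and 5 adjusted over the list alone), with Cd74 at -1.08 (SE 0.18). Set against other genes, the list had an adjusted p = 0.00463, and an adjusted p = 0.236 with an estimated correlation. The respiratory chain had 0 higher and 3 lower of 19 (0 and 8 adjusted over the list alone), with a median of -0.39, or -0.24 without IL-4 replicate 3 (adjusted p = 0.000172). For this list the test gave adjusted p = 1.48e-05, and adjusted p = 0.391 with an estimated correlation. Cholesterol biosynthesis had 0 higher and 5 lower of 20 (1 and 9 adjusted over the list alone). As a group they had an adjusted p = 0.000946, and an adjusted p = 0.106 with an estimated correlation. The cell cycle list had 2 higher and 8 lower of 31 (3 and 12 adjusted over the list alone), with Plk1 at -0.75 (SE 0.09), and its median of -0.17 became 0.02 with median centring (adjusted p = 0.163). Tested together they had an adjusted p = 0.0126, and an adjusted p = 0.25 with an estimated correlation. Fatty acid oxidation had 0 higher and 5 lower of 19 (1 and 8 adjusted over the list alone), and its adjusted p was 0.0574 without IL-4 replicate 2 and 0.136 with median centring. The list had an adjusted p = 0.0126, and an adjusted p = 0.0884 with an estimated correlation. Iron handling had 5 higher and 1 lower of 14, the same adjusted over the list alone (adjusted p = 0.0374, and adjusted p = 0.257 with an estimated correlation), with adjusted p of 0.107 without IL-4 replicate 2, 0.0609 without LPS replicate 3 and 0.148 after the filter on low values. Its median of 0.06 was -0.0096 without LPS replicate 1, 0.13 without LPS replicate 2, and 0.034, 0.024 and 0.0998 without IL-4 replicates 1, 2 and 3. The scavenger and phagocytic receptors had 3 higher and 8 lower of 29 (7 and 10 adjusted over the list alone). Its list test gave an adjusted p = 0.0455, and an adjusted p = 0.185 with an estimated correlation. That call ended without control replicate 2 (0.0509), control replicate 3 (0.0552), IL-4 replicate 3 (0.0957) or LPS replicate 3 (0.0741). It ended as well after quantile normalization (0.123), with the offset at the 40th percentile (0.0512), with array weights (0.0543), in a fit of those 6 arrays alone (0.0525) and with the replicate number as a block (0.0744).

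Among the lists that were not called between LPS and IL-4, several held genes called in both directions. Anti-inflammatory regulators had 6 higher and 5 lower of 21 (6 and 7 adjusted over the list alone; adjusted p = 0.397), with Tnfrsf1b at 2.29 (SE 0.10) and Cish at -2.10 (SE 0.18). Matrix proteases had 5 higher and 3 lower of 21 (6 and 3 adjusted over the list alone; adjusted p = 0.336), and eicosanoid metabolism 5 and 2 of 20 (5 and 3 adjusted over the list alone; adjusted p = 0.60). The unfolded protein response had 4 and 2 of 19 (4 and 2 adjusted over the list alone; adjusted p = 0.60) and the Toll-like receptor pathway 3 and 2 of 21 (3 and 3 adjusted over the list alone; adjusted p = 0.791). For these 5 lists the median was negative, at -0.19, -0.17, -0.16, -0.05 and -0.07, while the test pointed up, and the mean was positive except for the Toll-like receptor pathway (-0.02). Arginine and polyamine metabolism had 4 higher and 2 lower of 15 (4 and 3 adjusted over the list alone; adjusted p = 0.248). Glycolysis had 5 and 2 of 19 (7 and 2 adjusted over the list alone; adjusted p = 0.154) and MHC class I presentation 4 and 0 of 15 (4 and 0 adjusted over the list alone; adjusted p = 0.197). After quantile normalization these last lists were called, with adjusted p of 0.0476, 0.000695 and 0.0274, and glycolysis also without IL-4 replicate 3 (0.0185). Tlr4 was lower under LPS than under IL-4 by a log2 difference of -1.26 (SE 0.10) and Tlr2 higher by 1.95 (SE 0.10).

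The changes under IL-4 and under LPS shared 122 called genes. Of the 157 genes IL-4 raised, 31 were also raised by LPS, against 5.87 for independent lists, and 34 were lowered by LPS, against 6.15. Of the 83 genes IL-4 lowered, 33 were also lowered by LPS, against 3.25 for independent lists, and 24 were raised by LPS, against 3.10. The numbers for independent lists are too low, since they take all genes as equally likely to be called. Of the called genes, 230 of 240 for IL-4 and 1364 of 1393 for LPS had a group mean above the median signal. Both tests also share 1 estimate of each gene's spread, which can add shared calls in any direction. The shared genes numbered 68 without control replicate 1, 53 without control replicate 2, 64 without control replicate 3, 80 without IL-4 replicate 1, 78 without LPS replicate 2, 55 with median centring and 35 without the intensity trend. Among the genes raised by both, there were 16 without control replicate 2, 18 without LPS replicate 1, 17 with median centring and 13 without the trend. The genes raised by IL-4 and lowered by LPS numbered 20, 18 and 20 without control replicates 1, 2 and 3, 9 with median centring and 10 without the trend. Those lowered by both were 17, 10 and 10 without control replicates 1, 2 and 3, 18 without IL-4 replicate 1, 19 without IL-4 replicate 3, 18 without LPS replicate 2, 14 with median centring and 8 without the trend. Those lowered by IL-4 and raised by LPS were 10, 9 and 10 without control replicates 1, 2 and 3, 13 without IL-4 replicate 1, and 13, 14 and 15 without LPS replicates 1, 2 and 3. They were 15 with median centring and 4 without the trend. Genes moving in opposite directions included Igf1, at 2.07 under IL-4 and -0.76 under LPS, Gpr183 at 1.32 and -2.08, the guanine deaminase Gda at 1.06 and -1.28, Cybb at -1.04 and 2.19, and the niacin receptor Hcar2 at -1.11 and 2.96. The LPS change of Igf1 was -0.63 with an adjusted p = 0.0669 without LPS replicate 1, and had an adjusted p = 0.0873 without the intensity trend. Of its 3 other probe sets, 2 were at -0.29 (adjusted p = 0.31) and -0.33 (adjusted p = 0.136) under LPS and not called. The IL-4 change of Hcar2 had an adjusted p = 0.118 in a fit of those 6 arrays alone. Over all 18193 genes, which are not independent replicates, the log2 changes correlated with r = 0.22 (Spearman's rho = 0.21), and 55.8% had the same sign. After the filter on low values r was 0.0936. Unchanged groups simulated against shared simulated controls gave a mean r of 0.50, a rho of 0.46 and 66.7%, since both changes subtract the same controls. An r of 0.50 follows from that design alone. Real changes enter only the observed r, so the observed and simulated r cannot be compared directly. The covariance was 0.0346 against 0.0410 in the simulation, a difference of -0.00644. The 3 control arrays cannot be divided into separate sets of at least 2 arrays, so part of the excess of genes changed in the same direction may come from the shared controls.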

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

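All tests in this part were planned, and the cause of the differences was not tested unless given. Leaving out 1 array gave 114 to 247 genes for IL-4 (240 with all arrays), 912 to 1771 for LPS (1393) and 1289 to 2255 for LPS against IL-4 (2085). Without the intensity trend the counts were 92, 826 and 1285; median centring gave 116 for IL-4 and array weights 2140 for LPS. An added 2-fold threshold left 70, 384 and 566 genes by its construction. The other alternatives stayed within 1.5 times of the counts. The replicate numbers did not pair the arrays: deviations of same-number arrays correlated at -0.134 to 0.0990, those of different numbers at -0.112 to 0.121, and 2 of 9 arrays correlated best with their own number. With the replicate block the counts were 170, 1157 and 1752. Lists past the threshold numbered 9 for IL-4, 15 for LPS and 13 for LPS against IL-4, and 3, 7 and 5 with an estimated inter-gene correlation; IL-4 had 4 after quantile normalization. Leaving out 1 array gave 5 to 11, 14 to 16 and 11 to 13. The respiratory chain's median under IL-4 turned to -0.0395 after quantile normalization, and lay between -0.0341 and 0.173 without 1 array. Other called lists whose medians turned were matrix proteases under IL-4, to -0.0544 after quantile normalization, and, between LPS and IL-4, cell cycle, to 0.0160 with median centring, and iron handling, to -0.00963 without LPS replicate 1; with lists that were not called, 91 of 1404 medians had the other sign. In the mean of probe sets, which for both genes took in some in the background range, Etfdh turned to 0.0464 and Tap1 to -0.0532 between LPS and IL-4. The correlation of the IL-4 and LPS changes was 0.0936 after the filter on low values, against 0.224. In simulated unchanged groups it was 0.501, a value fixed by their design. Over all alternatives, values of named genes were the same in call and direction 4824 times, lost their call 421 times, gained it 8 times and reversed 2 times; for lists, by the sign of the list test and not of the median, this was 1323, 63, 16 and 2. Of called named genes, 33 of 49 for IL-4, 84 of 97 for LPS and 78 of 101 for LPS against IL-4 held in all 9 fits without 1 array. Signal over background limits genes under 71.3, the 95th percentile of the bacterial probe sets (64.8 without IL-4 replicate 3), whose fold rests on the offset.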

Other observations

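Of the tests in this part, those on other splits of the arrays, on bright lists and on genes moving in opposite directions were chosen only after the result was seen, while those on IL-4 replicate 3 were not.

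Part of the markers of alveolar macrophages lay in the background range in these cells. Of the 20 genes listed for that identity, 8 had group means under 71.3, the 95th percentile of the bacterial probe sets, in all 3 groups, and 11 under 104.6, the highest bacterial signal on the 8 arrays other than IL-4 replicate 3 (15 under 177.9, the highest on that array). The lectin Siglecf read 19.7, 5.30, 5.77 in control, IL-4 and LPS cells, and the lipid droplet protein Cidec 33.5, 17.6, 31.1, genes chosen after their values were seen. The tetraspanin Cd9 read 6339, 5526, 4782, the GM-CSF receptor chain Csf2rb 3328, 3247, 3361 and the cholesterol exporter Abcg1 1755, 2569, 2107, of which Cd9 and Csf2rb were chosen after their values were seen. In the list, 2 rose and 0 fell under IL-4 (2 and 0 adjusted over the list alone; adjusted p = 0.663), 0 and 0 changed under LPS (0 and 0; 0.347), and 0 were higher and 3 lower between LPS and IL-4 (0 and 3; 0.34). At an unadjusted p under 0.05 these numbers were 6, 6 and 7. The risers were Mrc1 and Abcg1, the latter at 0.54 (SE 0.11, adjusted p = 0.0393) and with calls in 3 of the 9 fits that leave out an array, its adjusted p reaching 0.182 without control replicate 3, and another of its probe sets was at 0.13 (adjusted p = 0.928). Under IL-4 the list's median was -0.04 while its mean of 0.12 and its test pointed up, and after the filter on low values, which drops the dim members, the list was called under IL-4 (adjusted p = 0.0119) and between LPS and IL-4 (0.0362).

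Of the markers of other cell types, 5 of 11 lymphocyte, 5 of 13 epithelial, 4 of 12 fibroblast and endothelial and 4 of 9 neutrophil genes had group means under 71.3 in all 3 groups, and 7, 7, 8 and 4 under 104.6. No such list was called over the 9 arrays in the deposited scaling. For IL-4, LPS and LPS against IL-4 the adjusted p were 0.0883, 0.752 and 0.14 for lymphocytes, 0.763, 0.818 and 0.744 for epithelium, 0.566, 0.23 and 0.52 for fibroblasts and endothelium, and 0.85, 0.249 and 0.318 for neutrophils. The lymphocyte list was called with median centring, for IL-4 at a median of 0.29 (adjusted p = 0.0286) and for LPS against IL-4 at -0.17 (0.0451), and for IL-4 also without control replicate 2 (0.0186) or IL-4 replicate 3 (0.0455). In the moderated test 0 of these genes were called under IL-4, where 1, 1, 0 and 2 had an unadjusted p under 0.05, and the neutrophil list's median of 0.09 lay above 0 while its mean of -0.03 and its test pointed down. Under LPS the antimicrobial peptide Camp was at 1.78 (SE 0.35, adjusted p = 0.00651) and the calcium-binding protein S100a8 at 1.12 (SE 0.19, adjusted p = 0.00256), and the proteoglycan Dcn was at 2.02 (SE 0.43, adjusted p = 0.0107), or 1.66 with an adjusted p = 0.0534 without control replicate 2. The control signals of Camp and Dcn lay in the background range. Between LPS and IL-4, Camp, S100a8 and Dcn were higher at 1.53, 1.65 and 1.78, with Camp at an adjusted p = 0.0617 without LPS replicate 1 and Dcn at 0.055 without IL-4 replicate 3, 0.0585 without LPS replicate 1 and 0.0702 without LPS replicate 2. The calls adjusted over each list alone were the same in number, as for Foxj1, lower between LPS and IL-4 at -1.17 (SE 0.32, adjusted p = 0.0356) from signals in the background range, with an adjusted p of up to 0.166 without LPS replicate 2.

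Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 split, gave as many genes in each comparison: 240 for IL-4 against control with 0 as the highest of the others, 1393 for LPS against control with 1, and 2085 for LPS against IL-4 with 0. So few splits cannot give a share under 0.05.

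IL-4 replicate 3 was brighter in its brightest probe sets than the other 8 arrays. Its hybridization spike-ins, which are added after the RNA is labelled, lay 1.75 log2 units above the other arrays and mouse probe sets of the same brightness 0.11, an excess of 1.65 against a mean of -0.20 (SD 0.38) on the others, 4.91 SD away, which argues against a brightness-dependent response of the whole array as the only cause. A stronger response to IL-4 in that sample cannot be told apart from an equal one: after quantile normalization the slope of its changes on those of the other IL-4 arrays was 0.876 (SE 0.0225), against 0.880 and 0.865 for replicates 1 and 2. The slope of replicate 3 was thus no larger than that of replicate 1, and these slopes differed by less than their SE. A larger amount of spike-in on that array may account for part of the excess of 1.65, and was not tested. The highest such excess among the other arrays, 0.58, was on IL-4 replicate 1.

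The respiratory chain and glycolysis lists stood higher under IL-4 with the preset correlation but not with an estimated one (adjusted p = 0.626 and 0.452). In the moderated test 0 of 19 members of each were called, where 1 and 4 had an unadjusted p under 0.05. Their 38 genes are bright. Their joint median log2 change was 0.15 with 9 arrays, where random lists of the same brightness gave 0.02 to 0.16 in their central 95% and 0.15 lay at the 95.6th percentile. Without IL-4 replicate 3 it was 0.0392 (random lists -0.04 to 0.06), and after quantile normalization -0.02. Since the joint median lay inside the range of random lists with 9 arrays already, its place inside that range without IL-4 replicate 3 does not single out that array, and the list calls also ended without control replicate 3. Whether the brightness of these genes on IL-4 replicate 3 raised the lists stays open, and no biological explanation was tested.

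Genes called lower under IL-4 and higher under LPS numbered 24, against 3.10 for independent lists, and those higher under IL-4 and lower under LPS 34, against 6.15. The numbers for independent lists are too low, since they take all genes as equally likely to be called while calls fell mostly on bright genes. An excess over them therefore cannot show an opposed response by itself. Noise in the mean of the shared control arrays moves both changes the same way, so that noise alone does not give the 24. Both tests also share 1 estimate of each gene's spread. A gene whose spread came out low is called more easily in both, in any direction, and this was not tested. There were 16 (against 2.67) without IL-4 replicate 3 and 25 (against 4.16) after quantile normalization. Such genes were thus still called without that array and with another scaling, so neither accounts for all of them. The number moved with the arrays, to 10 (against 1.34), 9 (0.674) and 10 (0.871) without control replicates 1, 2 and 3, 13 (1.84) without IL-4 replicate 1, 13 (1.74), 14 (1.45) and 15 (1.98) without LPS replicates 1, 2 and 3, and 4 (0.41) without the intensity trend. Of the fits that leave out 1 array, those without a control array gave the lowest numbers. The pattern was first posed for all 680 genes LPS raised, whose median IL-4 change of -0.0127 did not show it, since unchanged genes of the same brightness gave -0.07 to -0.03; shared controls push this median up, which keeps it open, and the counts were tested afterwards. A lower level of NF-kB target genes under IL-4 stays open: the list's median of 0.05 lay inside the central 95% of random lists of the same brightness (-0.14 to 0.08), and at 0.09 without IL-4 replicate 3 just above theirs (-0.11 to 0.08), its members went both ways, with 3 higher and 4 lower at an unadjusted p under 0.05, and 1 of the 24 genes, Nfkbiz, belongs to it. Of the interferon-stimulated list, already reported as lower under IL-4, 2 of the 24 genes are members, Ifit1 and Ifit3, and the median of the list was -0.15 (random lists -0.06 to 0.08) and -0.11 after quantile normalization. Without 1 array the median was -0.17 (IL-4 replicate 3) to -0.0994 (IL-4 replicate 1, random lists -0.06 to 0.10). Without these 2 genes it was -0.11 (random lists -0.07 to 0.08). These 2 genes thus stood lower under IL-4 together with the other interferon-stimulated genes on the same arrays. That describes their fall and gives no cause for it, and it says nothing of the rest of the 24. The list does not hold every interferon-inducible gene, as Cxcl10, described above as interferon-inducible, is another of the 24. Random lists were drawn gene by gene, so they do not carry a correlation among the listed genes.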
